A study of Mus musculus with 58 samples.

How the data were processed

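Genomic DNA was extracted from brain samples by phenol extraction and hybridised, after bisulphite conversion, to a custom Illumina GoldenGate methylation array with Cy3 and Cy5 label, per the labels' protocols and the series design. The values used are the authors' deposited beta values, a fraction from 0 to 1 per CpG and array, for 382 CpGs and 58 arrays. Scanner software, background correction, normalization and filters are not given in the sources used here, nor is a genome build, so no coordinates are printed. No value was missing, and all lay between 0.0196 and 0.986. Bead numbers and signal over background per value were not used here.

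Each CpG carries a gene name and a number whose meaning is not given in the sources used here. Of the names, 362 matched a current symbol in a RefSeq table (GRCm38.p6) and 20 matched a synonym, which gave 17 X-linked and 365 autosomal CpGs. Nr3c1 has more than 1 CpG.

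Samples were grouped by the tissue and genotype labels. CPU M4 was run on a pair of arrays, M4_a and M4_b, which correlated at 0.987, within the range of other CPU pairs (0.966 to 0.997), and their mean was used as 1 replicate. Among 1653 pairs of arrays none was identical. Replicate codes such as F1 or M4 recur across regions, and the labels do not say that they mark animals.

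Tests were made with limma 3.58.1 in R 4.3.3 on log2(beta / (1 - beta)), with beta limited to between 0.01 and 0.99, moderated variances (eBayes) and Benjamini-Hochberg adjustment over the 382 CpGs, at an adjusted p under 0.05. One fit over the 53 samples of 11 regions gave an F-test of any regional difference, each region minus the unweighted mean of the other 10, and CA3 minus DG, PC minus GCL and CPU minus GP. The 3TG comparison used a fit over all 13 groups, so that they share an estimate of the spread. F-coded minus M-coded samples were tested with region as a covariate and the replicate code as a random block (duplicateCorrelation). The estimated correlation within a code was 5.45e-05, so the block had almost no effect and the samples entered nearly as independent. Nearest neighbours and the median correlation within minus between regions were tested by 100000 permutations of the region labels. Gene lists were tested with Fisher's exact test from 3 CpGs and with camera (preset correlation 0.01, and an estimated one) and fry from 5 CpGs. The lists of epigenetic and tumour suppressor genes had 0 CpGs on the array. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were also used.

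The choices of tests, groups, lists and named genes were made before the data were examined. Named genes were, with 1 CpG per gene, the 15 widest by the F-test, for each region the 3 widest calls and the 2 widest of the other direction where those lack it, 5 per pair of regions, up to 20 for 3TG together with 4 genes the study is known for, 10 for the code letters and 4 per list.

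The fits were tested on simulated arrays with independent noise of the real spread at each CpG, 20 times over the same 382 CpGs. In each, 20 CpGs were changed by each of 0.5, 1 and 2 on the log2 scale. A change of 1 was recovered at 97.8% of CpGs for GCL against the other regions, 91.8% for FC_WT, 93.3% for the F-test, 91.0% for PC minus GCL, 71.8% for 3TG minus wild type and 99.5% for F minus M. For a change of 0.5 these shares were 78.5%, 37.75%, 44%, 47%, 17.75% and 94%. Of the calls in these simulations, 4.15% to 5.51% were false. The simulated arrays had no shift of a whole array and no correlation between CpGs, so these rates need not hold for the real arrays. The first quartile of beta of the real arrays ran from 0.0456 to 0.0995.

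Alternatives tried were untransformed beta, wider limits on beta, quantile normalization, centring on the array median, a filter on mean beta under 0.05 or over 0.95, leaving out X-linked CpGs, minimum differences of 0.1 and 0.2, robust trended variances, either CPU M4 array alone, the replicate code as a block, the code letter as a covariate, leaving out FC_WT, DG F7 to F9 or each sample in turn, a fit of the 5 frontal cortex samples alone, 1 value per code, other measures of correlation and distance, and, chosen after the data were seen, leaving out PC F2 and M3, these with GP M3 and DG F7 to F9, or codes F7 to F9, and counting PC and GCL as 1 region.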

Results

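Methylation was measured at 17 X-linked and 365 autosomal CpGs, each named for 1 of 381 genes, in genomic DNA from dissected mouse brain. The assay was a custom Illumina GoldenGate array, a bead array that reads the methylated and the unmethylated form of each CpG after bisulphite conversion, and each value is a beta value, the methylated share of the signal from 0 to 1. Of 58 arrays, those of 11 regions of C57BL/6 mice gave 53 samples: basolateral amygdala (BLA, n = 5), CA3 (n = 4), caudate-putamen (CPU, n = 6), dentate gyrus (DG, n = 5), wild-type frontal cortex (FC_WT, n = 2), granular cell layer (GCL, n = 6), globus pallidus (GP, n = 5), hypothalamus (HYP, n = 5), Purkinje cells (PC, n = 4), substantia nigra (SN, n = 6) and thalamus (TH, n = 5). A further 3 samples were frontal cortex and 1 was CA1 from mice labelled 3TG, whose labels name another genetic background. The number of arrays limits the precision. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples only.

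Most of the CpGs had low methylation. Mean beta over the 53 samples was under 0.2 at 242 CpGs, between 0.2 and 0.8 at 102 and over 0.8 at 38. Mean beta per array lay between 0.249 and 0.294. Whole profiles grouped by region: for 35 of the 53 samples the best correlated other sample came from the same region, against a mean of 4.17 with permuted region labels (one-sided permutation test, p = 1e-05, the smallest that the permutations can give). The grouping was complete for TH, with 5 of 5 samples, and for FC_WT, with 2 of 2, and weakest for GP, with 1 of 5. In DG, F7, F8 and F9 matched one another, while F3 matched GP F2 and M2 matched CA3 M4. FC_WT and DG F7 to F9 share a form of title, so region and a batch cannot be told apart for them. Each sample whose replicate code carries the letter F or M was best correlated with a sample of the same letter. The letter thus went with the grouping too. The median correlation of sample pairs was 0.984 within regions and 0.973 between regions, a difference of 0.0114 (one-sided permutation test, p = 1e-05, likewise the smallest possible). With Spearman correlation the count was 18, and over the 100 CpGs of largest variance the difference was 0.0543, both with p at that smallest value.

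The question set by the series title, how methylation differs across regions of the healthy brain, was addressed first over all 11 regions. Methylation differed between regions at 170 CpGs (limma F-test, Benjamini-Hochberg adjusted p under 0.05), with region means at least 0.1 apart at 86 of them and at least 0.2 apart at 44. The widest range was that of Cacna1d, an L-type calcium channel subunit, from 0.320 ± 0.0550 (SD, n = 6) in GCL to 0.806 ± 0.0277 (SD, n = 5) in TH. Ush1g, a scaffold protein of sensory hair cells, ran from 0.256 ± 0.00339 (SD, n = 2) in FC_WT to 0.687 ± 0.0355 (SD, n = 4) in PC. Glutamate and GABA receptor genes were among the widest: Grin2c ranged from 0.150 in GCL to 0.530 in HYP, Gabra6 from 0.237 in GCL to 0.580 in FC_WT and SN, and Grin2a from 0.132 in FC_WT to 0.472 in CPU. The other wide ranges were at Mas1, Ide, Pthr1, Tbxa2r, Sstr3, Tbx1, Gfap, Sorbs3, F2rl2 and Cnr2, with differences between the highest and lowest region from 0.331 at Cnr2 to 0.382 at Mas1.

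**Figure D1:**
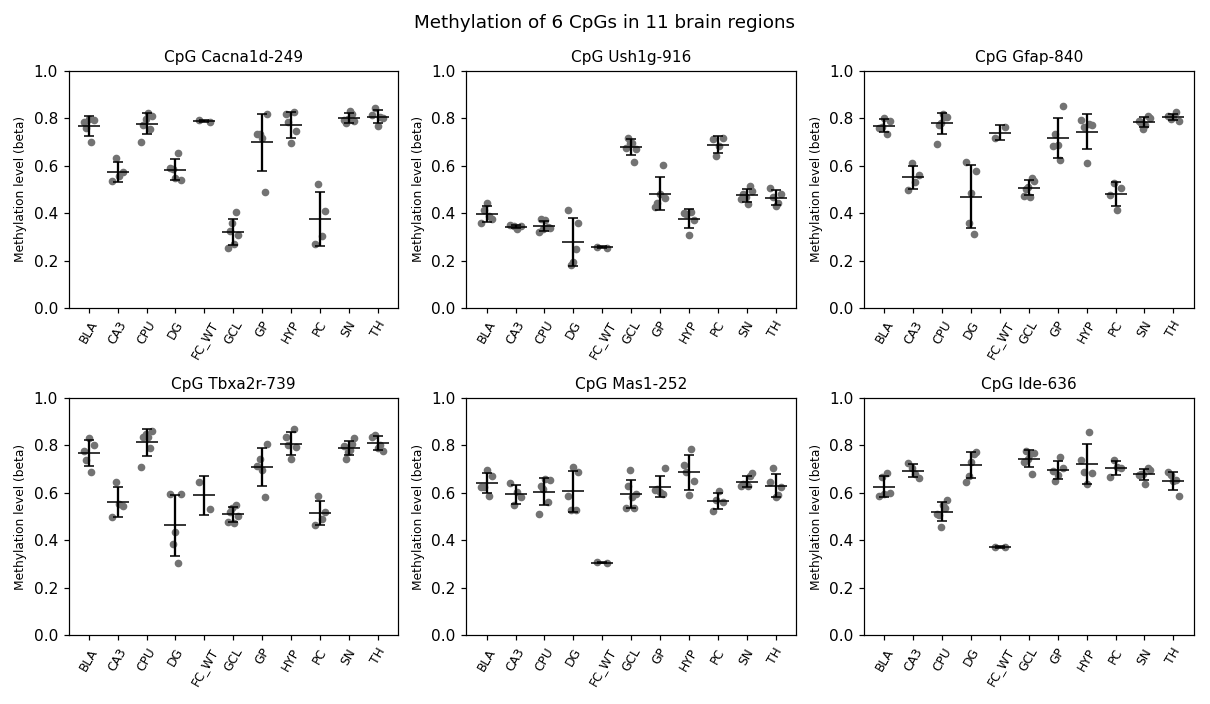
Beta values (vertical axes, 0 to 1) of 6 CpGs in the 11 regions. Grey points are samples, horizontal bars are means and error bars are SDs; GCL and PC lie lowest at Cacna1d and highest at Ush1g, DG and PC lie lowest at Gfap, and the 2 FC_WT samples lie below the other regions at Mas1 and Ide.

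PC and GCL, the labels that name cell layers, shared a set of genes with low or high methylation. Cacna1d was at 0.320 in GCL and 0.375 ± 0.113 (SD, n = 4) in PC, against 0.694 and 0.689 for the mean of the respective other regions (adjusted p = 1.75e-15 and 1.47e-10). The parathyroid hormone receptor gene Pthr1 was likewise low in both, at 0.245 ± 0.0324 (SD, n = 6) and 0.257 ± 0.0708 (SD, n = 4), where other regions averaged 0.520 and 0.519. Ush1g went the other way, at 0.677 and 0.687 against 0.411 and 0.409. Among the receptor genes, Sstr3 was at 0.0902 in GCL and 0.136 in PC, Grin2c at 0.150 and 0.181, and Gabra6, whose protein is a GABA-A receptor subunit of cerebellar granule cells, at 0.237 and 0.278.

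GCL differed from the other regions at 85 CpGs (31 higher, 54 lower; 71 and 50 with quantile normalization, 56 and 45 with each array centred on its median). PC differed at 178, with 133 higher and 45 lower (77 and 52, and 58 and 49, with the same normalizations). These tests were against no difference, while the median log2 difference over all CpGs was 0.20 in PC. The counts of 133 and 45 are thus not relative to that median. Of the 35 GCL calls with a difference of 0.1 or more, 35 had the same sign in PC and 33 were called there. Both were called higher at 20 CpGs and lower at 40, where independent lists would share 10.8 and 6.36. Their log2 differences from the other 9 regions correlated across CpGs, which are not independent replicates, at r = 0.902. Simulated groups without effects gave 0.123, and with the other regions divided between the comparisons r was 0.899. PC minus GCL gave 0 CpGs by limma, with 95 at an unadjusted p under 0.05 and 31 called on untransformed beta. It gave 75 CpGs without PC F4, 49 without PC F1, 9 without DG F9, 7 without HYP M1, 5 without HYP F2 or GCL M3 and 1 without GCL F2. Most of the higher calls in PC were small: 4 reached 0.1, against 28 of the lower ones. PC F2 and PC M3 had the highest first quartiles of beta in PC, at 0.0759 and 0.0995, against 0.0555 and 0.0543. Without both, a choice made after the data were seen, PC differed at 59 CpGs (14 higher, 45 lower), and without M3 or F2 alone at 62 and 110.

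In the hippocampal fields CA3 and DG, Gfap, the astrocyte intermediate filament, was at 0.550 ± 0.0485 (SD, n = 4) and 0.469 ± 0.133 (SD, n = 5), against 0.679 and 0.687 for the mean of the respective other regions, of which PC and GCL were at 0.481 and 0.507. F2rl2, a protease-activated receptor gene, was at 0.693 ± 0.0548 (SD, n = 4) in CA3 (adjusted p = 0.00082) and at 0.601 ± 0.107 (SD, n = 5) in DG (adjusted p = 2.77e-09), while the means of the respective other regions were 0.814 and 0.824 and FC_WT was at 0.615. Grin2a, an NMDA receptor subunit gene, was at 0.194 ± 0.020 (SD, n = 4) in CA3, 0.178 in DG and 0.132 in FC_WT. In DG the thromboxane receptor gene Tbxa2r was at 0.463 ± 0.130 (SD, n = 5) against a mean of 0.687 elsewhere, with 0.509 in GCL and 0.515 in PC (adjusted p = 3.12e-07). The adenylate cyclase gene Adcy9 was higher in DG, at 0.410 ± 0.266 (SD, n = 5) against 0.192, a call lost without DG F7 or F9 (log2 differences of 0.98 and 1.19, against 1.54 with all). The F-test over all regions did not call Adcy9 (adjusted p = 0.129).

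CA3 differed from the other regions at 8 CpGs (0 higher, 8 lower; 7 and 13 with quantile normalization), and DG at 92 (30 higher, 62 lower; 51 and 63). CA3 and DG differed from each other at 25 CpGs, 22 of them higher in CA3 (9 of 15 with quantile normalization). The muscarinic receptor gene Chrm2 was at 0.769 ± 0.0125 (SD, n = 4) in CA3 and 0.655 ± 0.119 (SD, n = 5) in DG (adjusted p = 0.0218), and Clic5, Adrb1 and Gal3st1 were also higher in CA3, by 0.0873, 0.0714 and 0.0540. The histamine receptor gene Hrh1 was lower in CA3, at 0.520 against 0.626. DG F7, F8 and F9 are the DG samples whose titles follow another scheme. Without them DG differed at 5 CpGs, CA3 and DG at 0, and Adcy9 in DG and Chrm2 between CA3 and DG changed sign; with the replicate code as a fixed block, which those 3 samples do not share with other regions, and without FC_WT, DG gave 0 as well. Without 1 sample, CA3 gave 1 (without F3 or M1, which also ended the calls of Gfap and Grin2a), 4 (F4) and 5 (M4, which ended that of Grin2a too), DG gave 43 (F9) and 44 (F8), and their comparison gave 0 (CA3 F3, DG F8 or DG F9), 2 (CA3 M4), 4 (CA3 F4) and 57 (DG F3). Over those losses in CA3 the log2 difference lay between -0.96 and -0.85 for Grin2a and at -0.77 and -0.83 for Gfap.

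Wild-type frontal cortex had low methylation at several receptor and enzyme genes. Mas1, a receptor gene of the angiotensin system, was at 0.305 ± 0.00216 (SD, n = 2) against 0.620 in the other regions, whose means lay between 0.567 and 0.687 (adjusted p = 3.23e-08). Ide, which encodes the insulin-degrading enzyme, was at 0.372 ± 0.00273 (SD, n = 2) against 0.675, and the adrenergic receptor gene Adra1b at 0.623 ± 0.00762 (SD, n = 2) against 0.900. The X-linked leukotriene receptor gene Cysltr1 was higher, at 0.329 ± 0.0128 (SD, n = 2) against 0.184, a mean that depends on the mix of codes: Cysltr1 was at 0.135 in samples coded F1 to F4, 0.222 in M-coded samples and 0.325 in DG F7 to F9. In all, 121 CpGs differed, 16 higher and 105 lower. The median log2 difference over all CpGs was -0.19 in FC_WT, and relative to it the balance changed: quantile normalization gave 73 higher and 71 lower, and centring each array on its median gave 82 and 43. Leaving out 1 of the 2 samples gave 52 calls without replicate 1_a and 64 without replicate 3, and the call of Cysltr1 was lost without either.

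Caudate-putamen had high methylation at 3 genes of receptors and adaptor proteins. Sorbs3, an adaptor protein gene, was at 0.576 ± 0.0743 (SD, n = 6) against 0.390 in the other regions, the metabotropic glutamate receptor gene Grm2 at 0.35 ± 0.0679 (SD, n = 6) against 0.172 (adjusted p = 9.59e-13), and Grin2a at 0.472 ± 0.0905 (SD, n = 6) against 0.30. Cysltr2 and Ide were lower, at 0.541 against 0.688 and at 0.521 against 0.661. The CPU calls numbered 38, of which 22 were higher. GP gave 0 CpGs against the other regions by limma, with 18 at an unadjusted p under 0.05, and 1 without GP M4. Between these nuclei of the basal ganglia, 23 CpGs differed (10 higher in CPU, 13 lower; 6 and 15 with each array centred on its median). Grm2, Sorbs3 and Grin2a were higher in CPU than in GP, at 0.35 against 0.177, 0.576 against 0.407 and 0.472 against 0.307, and Ide and the galanin receptor gene Galr3 were lower, at 0.521 against 0.696 and 0.50 against 0.651. Without GP F1 the call of Grin2a between CPU and GP was lost.

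In the remaining regions most calls were higher than the mean of the other regions. That mean takes in regions with low levels, such as GCL at Cacna1d (0.320) and Tbx1 (0.113). In BLA, Grin2c was at 0.506 ± 0.0525 (SD, n = 5) against 0.359, the thrombin receptor gene F2r at 0.541 ± 0.0354 (SD, n = 5) against 0.407 and Sstr3 at 0.418 against 0.30, while Crhr2 was lower, at 0.438 against 0.518. In HYP the calcitonin receptor gene Calcr was at 0.395 ± 0.0963 (SD, n = 5) against 0.204, and Sorbs3 and Grin2c were higher by 0.175 and 0.174, with Hrh1 and Tacr2 lower. SN and TH both had high levels at Tbx1, a T-box transcription factor gene, with 0.439 ± 0.0284 (SD, n = 6) and 0.449 ± 0.0530 (SD, n = 5), and at Cacna1d, with 0.801 and 0.806. The neuromedin receptor gene Nmur2 was higher in SN, at 0.434 against 0.277, and Gje1 and Gabrr1 were lower there. Tbxa2r was higher in TH, at 0.809 against 0.652, and P2ry5 and Hrh4 were lower there. The counts were 26 in BLA (25 higher), 38 in HYP (33 higher), 57 in SN (48 higher) and 27 in TH (21 higher). With quantile normalization the higher and lower calls numbered 19 and 5 in BLA, 37 and 22 in HYP, 32 and 12 in SN and 21 and 14 in TH, and with centring 23 and 1, 26 and 22, 46 and 8, and 12 and 5. Region pairs differed at 0 CpGs for BLA with GP and for SN with TH, and at up to 205 for PC with SN. Among BLA, HYP, SN and TH no pair differed at more than 4 CpGs. Their higher calls thus set them apart mainly from other regions. Leaving out BLA M1 or M4 gave 16 and 13 BLA calls, and leaving out TH F2 or F4 gave 15 and 13 TH calls. SN gave 36 calls without SN M3. Several lower calls were lost with 1 sample left out: Gabrr1 without SN M3 or F4, Tacr2 and Hrh1 without HYP F4, Hrh4 without TH M1 or M4, P2ry5 without any TH sample or FC_WT 1_a, and Crhr2 without any of 30 samples. The log2 difference of Gabrr1 was -0.58, and -0.28 without SN M3, and that of Tacr2 was -0.60, and -0.31 without HYP F4. Crhr2 lay near the threshold and kept a log2 difference of -0.47 to -0.42 over those losses, and Hrh1 was at -0.44 without HYP F4, against -0.53 with all samples. The F-test over all regions did not call Crhr2 (adjusted p = 0.139).

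Gene groups fixed before the data were examined showed no enrichment among the CpGs that differed between regions (Fisher's exact test, two-sided, adjusted p = 0.192 or more, 2 lists at an unadjusted p under 0.05). With the replicate code as a fixed block and without FC_WT, the ion channel CpGs (9 of 15) and the 4 genes the study is known for were enriched. Of the ion channel CpGs, 10 of 15 differed between regions (11 adjusted over the list alone, the only list whose counts differ), among them Cacna1d, P2rx1, Kcnip1 and Trpv1, whose call was lost without any of 4 samples. Kcnip1, a potassium channel interacting protein gene, was at 0.0494 ± 0.0115 (SD, n = 6) in GCL and 0.273 ± 0.0220 (SD, n = 6) in SN. In GCL 7 of the 15 were lower and 1 higher, with a camera adjusted p of 0.111, and an adjusted p of 0.994 with an estimated correlation. Of the glutamate and GABA CpGs 18 of 43 differed (18 adjusted over the list alone), as did 10 of 25 of the dopamine and monoamine group, led by Adra1b and Adra2c. Both astrocyte markers differed, Gfap as above and Slc1a3 between 0.145 in FC_WT and 0.241 in PC. Of the oligodendrocyte markers 1 of 6 did, Gm98 (now Myrf), from 0.319 in PC to 0.503 in HYP. The neuronal markers Gap43 and Reln and the immune gene Ifng did not pass, with region means of 0.282 to 0.396, 0.129 to 0.169 and 0.856 to 0.899. Of the Alzheimer group Ide and Mme differed (Mme from 0.124 in FC_WT to 0.177 in PC, a call lost without any of 6 samples) and Cdk5r1 and Cdk5 did not. The groups of homeobox and patterning genes (3 of 10), sensory genes (2 of 5, Ush1g and Ush1c), imprinted genes (1 of 2, Sgce), synaptic genes (1 of 2), movement disorder genes (0 of 2), neurotrophin genes (0 of 3) and cell death and stress genes (0 of 6) completed the lists with CpGs, besides the endothelial list, whose only CpG is Tbxa2r. Of 105 camera tests 0 passed with either correlation, 9 at an unadjusted p under 0.05 with the preset one and 0 with the estimated one, while fry, which compares no list with other genes, called 10, the ion channel CpGs in GCL (adjusted p = 6.72e-08), PC, BLA, HYP and SN among them. The 4 genes the study is known for, Tbxa2r, Sorbs3, Spnb4 and F2rl2, all differed between regions (4 adjusted over the list alone), which is not independent evidence since the study chose them.

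Frontal cortex of 3TG mice was then compared with that of wild-type mice, the only comparison of genotypes within a region. Spnb4 (now Sptbn4), which encodes a spectrin of the axon initial segment, was lower in 3TG, at 0.324 ± 0.0202 (SD, n = 3) against 0.549 ± 0.0586 (SD, n = 2), with a limma adjusted p of 0.00562. F2r was also lower, at 0.328 ± 0.128 (SD, n = 3) against 0.497 ± 0.00364 (SD, n = 2), adjusted p = 0.0232. Higher in 3TG were Prlhr, at 0.163 ± 0.00556 against 0.0751 ± 0.0202 (adjusted p = 0.00401), and the cell cycle inhibitor gene Cdkn1b, at 0.0692 against 0.0391. In all, 5 CpGs were called, and at all 5 the 3 samples lay on the same side of both wild-type samples. Of the other genes the study is known for, F2rl2 was at 0.780 ± 0.0361 (SD, n = 3) against 0.615 ± 0.0120 (SD, n = 2), adjusted p = 0.188, Tbxa2r at 0.646 against 0.590 and Sorbs3 at 0.329 in both groups, none of them called. Over all CpGs the ranges of the groups did not overlap at 114, or 29.8%, where chance gives 20%. Within the list of 4 study genes 2 passed when adjusted over the list alone, which is not independent evidence. Genotype and genetic background differ together here. The form of title differs in part as well. Both wild-type titles contain CxF, as does that of FC_3TG 2_a, while FC_3TG F10 and F12 have titles of another form. A batch that goes with the form of title was not tested for this comparison. Without FC_WT 1_a Spnb4, F2r, Prlhr and Cdkn1b all lost the call, at log2 differences of -1.11, -1.08, 0.99 and 0.76. Without FC_3TG F12 3 CpGs were called and Cdkn1b lost the call, at 0.78, and F2r lost it without any of 4 samples. F2rl2 passed with only the 5 frontal cortex samples in the fit or on untransformed beta.

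**Figure D2:**
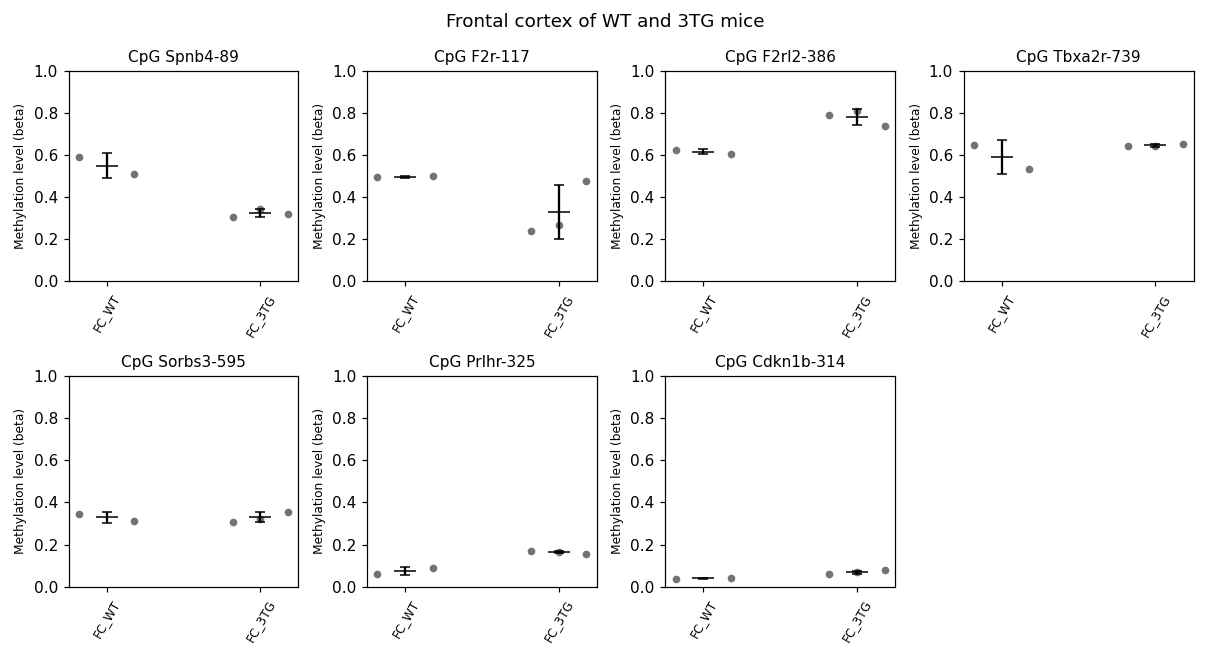
Beta values (vertical axes, 0 to 1) of 7 CpGs in frontal cortex of wild-type (n = 2) and 3TG (n = 3) mice. Grey points are samples, bars are means and error bars are SDs; Spnb4 and F2r lie lower in 3TG, at 0.324 and 0.328, and Prlhr and Cdkn1b lie higher from low levels.

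Samples of 10 regions carry a replicate code with the letter F or M, whose meaning the labels do not give. F-coded (28 samples, 7 codes) and M-coded samples (23 samples, 4 codes) differed at 15 CpGs, and all 15 were among the 17 X-linked CpGs, against 0 of 365 autosomal CpGs by limma (13 at an unadjusted p under 0.05). Of the 15, 14 were lower in F-coded samples. The widest was Gabrq, a GABA-A receptor subunit gene, at 0.254 ± 0.133 (SD, n = 28) against 0.732 ± 0.0244 (SD, n = 23). The adhesion molecule gene L1cam was at 0.207 against 0.519, Gria3 at 0.383 against 0.611, Gpr50 at 0.319 against 0.528 and Glra2 at 0.302 against 0.505. Gabre, Htr2c, Pja1 and Pou3f4 were also lower, with differences of -0.199, -0.196, -0.175 and -0.165. P2ry10, named after its values were seen, was the exception, at 0.505 in F-coded and 0.446 in M-coded samples. The F-coded samples were not uniform. Mean X-linked beta lay between 0.310 and 0.385 in the 25 samples coded F1 to F4, between 0.466 and 0.521 in DG F7, F8 and F9, and between 0.468 and 0.540 in the M-coded samples. It was at 0.457 in CA1_3TG F2, 0.454 in FC_3TG F10 and 0.439 in FC_3TG F12, which also carry the letter F and were not compared. No interaction of letter and region was called at any CpG over 8 regions and 42 samples (smallest limma adjusted p = 0.870, 18 CpGs at an unadjusted p under 0.05). DG and PC, with too few M-coded samples, were left out, so DG F7 to F9 did not enter that test. Quantile normalization gave 16 X-linked and 13 autosomal calls. Without the random block the calls were 15 X-linked and 0 autosomal, as with it, and with 1 value per code 6 X-linked CpGs passed.

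**Figure D3:**
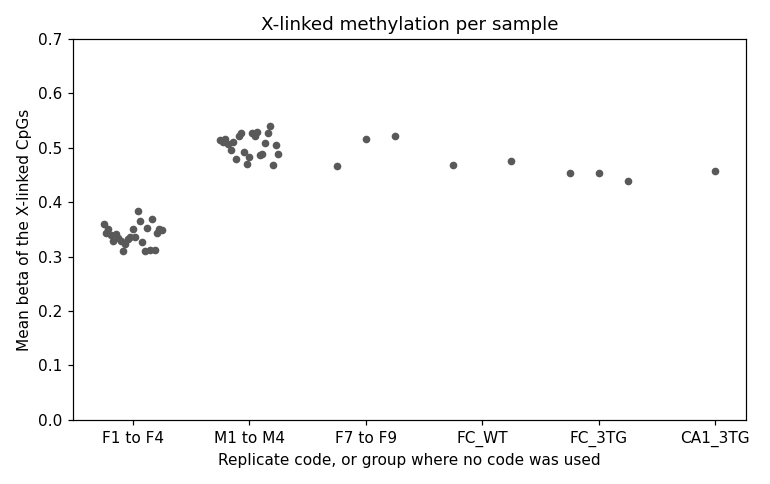
Mean beta of the 17 X-linked CpGs (vertical axis) per sample, by replicate code or, where none was used, by group. Each point is a sample; the samples of the 10 regions coded F1 to F4 lie between 0.310 and 0.385, and every other sample, the CA1 sample F2 among them (0.457), lies at 0.439 or above.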

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

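The tests of the X-linked pattern were chosen after its values were seen; the tests of GP M3 were set before their values were computed, but after its nearest neighbours had been seen.

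In 9 of 139 region values tested, 1 sample stood further from the others than Dixon's 95% critical value allows, where chance gives about 6.95. Gabre in PC M3 was 0.322, against 0.0450 to 0.0701 in the other PC samples, and Pou3f4 in PC M3 was 0.328, against 0.0775 to 0.0869. Pou3f4 in DG F3 was 0.0734, against 0.222 to 0.279. Both genes are X-linked. PC M3 was the only M-coded PC sample, and DG F3 the only DG sample coded F1 to F4. Gabre averaged 0.0533 ± 0.0109 (SD, n = 25) in samples coded F1 to F4. In M-coded samples it averaged 0.2996 ± 0.0302 (SD, n = 23). Pou3f4 averaged 0.0784 ± 0.0121 (SD) and 0.262 ± 0.0356 (SD) in these groups, and 0.249 in DG F7 to F9. The flagged values of both genes thus lay nearest the mean of their own codes, which includes them. Gabrr1 in SN M3 was 0.423, against 0.653 to 0.738. Grm2 in GP F1 was 0.144, against 0.181 to 0.192. Kcnip1 in GCL M3 was 0.0717, against 0.0394 to 0.0494. Sgce in TH F4 was 0.494, against 0.640 to 0.671. Tacr2 in HYP F4 was 0.707, against 0.852 to 0.885. Galr3 in GP M3 was 0.724, against 0.621 to 0.649.

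GP M3 resembled PC and GCL. Its best correlated sample was GCL M4 (r = 0.994), and Cacna1d, at 0.491 in GP M3, was between 0.716 and 0.816 in the other GP samples. Over 60 autosomal CpGs called in both PC and GCL without it, GP M3 lay 0.657 of the way from the other GP samples to PC and GCL, where the other GP samples lay between -0.286 and 0.174. CpGs alike in PC, GCL and the other regions deviated by 0.0113 in GP M3, within the 0.0101 to 0.0117 of the other GP samples. This cannot decide on poor array signal: signal values were not used, and GP M3 was set against a mean of more samples than the others were. A swap with a PC or GCL sample of this series is argued against, since none of those lay more than 0.342 of the way to the other regions. Those samples also took part in the choice of the 60 CpGs, and a swap with a sample outside the series was not tested. DNA of PC or GCL samples mixed in may account for the position of 0.657, whereas a mislabelled sample, for which 0.8 was set, cannot be told apart from it, the spread of the other GP samples being 0.203; no biological explanation was tested.

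The X-linked difference between code letters was in the direction opposite to that expected if F marked females, in which the inactive X carries methylated promoters: 14 of the 15 called CpGs were higher in M-coded samples. A difference in arrays or processing is argued against by 0 autosomal calls by limma, with 13 at an unadjusted p under 0.05, though quantile normalization gave 13 autosomal calls. M-coded samples may carry an active and an inactive X, but 1 CpG, Gabrq, at 0.732, lay above the bound of 0.606 that full methylation of an inactive X would set; beta values were not calibrated, so this explanation cannot be told apart from others. In splits of the 11 codes, 12 of 100 gave as many calls as the 15 found, and the highest other split gave 19. The splits thus do not exclude chance at the level of codes. Of the 11 other such splits, 4 kept F1 to F4 together, as did 11 of all the other splits drawn, and the highest parted them. Splits that set F1, F2 and F4 apart with F7, F8, M1 or M3 gave 17, 17, 18 and 14 calls. Near repeats of the contrast are thus counted as chance, and the splits cannot decide. Mean X-linked beta of F1 to F4 did not overlap that of M-coded samples, while that of F7 to F9 did.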

How the results depend on the processing

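The alternatives without PC F2 and M3, without these and GP M3 and DG F7 to F9, without codes F7 to F9 and with PC and GCL as 1 region were chosen after the data were seen. Where no construction is named below, the cause was not tested. Wider limits on beta changed nothing, since no value lay outside 0.01 to 0.99. Untransformed beta gave 7 CpGs for CA3 and DG and 31 for PC and GCL. Quantile normalization gave 20 for CA3, 59 for HYP, 15 for CA3 and DG and 29 for the code letters. Centring on the array median gave 107 for PC, 17 for TH and 5 for CA3 and DG. Leaving out X-linked CpGs gave 0 for the code letters. A difference of at least 0.1, which only removes calls, left 86 for the F-test, 10 for BLA, 5 for CA3, 16 for CPU, 13 for DG, 36 for FC_WT, 35 for GCL, 15 for HYP, 32 for PC, 16 for SN, 9 for TH, 2 for CA3 and DG and 2 for 3TG; one of at least 0.2 left 44, 0, 0, 0, 4, 8, 9, 0, 9, 0, 0, 0 and 1, with 0 for CPU and GP and 5 for the code letters. Without FC_WT CA3 gave 13. Without DG F7 to F9, DG gave 5, CA3 and DG 0 and PC and GCL 16. The code letter as a covariate, which also leaves out FC_WT for want of a letter, gave 15 for CA3 and 39 for CA3 and DG. Only the 5 frontal cortex samples gave 8 for 3TG, and 1 value per code gave 6 for the code letters, against 18 without codes F7 to F9. Without PC F2 and M3, PC gave 59; without these, GP M3 and DG F7 to F9, CA3 gave 20, DG 8, GP 5, PC 67 and CA3 and DG 0. For gene lists, camera gave 0 calls with either correlation and fry, which compares no list with other genes, gave 10.

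With the code as a fixed replicate block, which also leaves out FC_WT for want of a shared code, the counts were 105 for the F-test, 13 for CA3, 0 for DG (135, 13 and 109 without FC_WT alone) and 0 for CA3 and DG, and 2 lists were enriched, ion channels and the study's genes. The block absorbs DG F7 to F9, whose codes occur in no other region. As a random replicate block no count moved by over 1.5 times. Of 149 pairs of samples with the same code 45 correlated above 0.1 over autosomal CpGs, with region and letter taken out. Their median was -0.0308, against -0.0398 for different codes of the same letter. Over all CpGs, with region alone taken out, these medians were 0.332 and 0.264. Of 51 samples 8 correlated best with their own code, for which no chance level was computed. This cannot decide whether the codes mark animals, and the main fit did not pair samples by code.

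Reversed signs, none of them past the threshold, were Sorbs3 in 3TG at -0.0440 (log2) with quantile normalization, -0.0592 with centring and between -0.112 and 0.121 with a sample left out, Tbxa2r in 3TG between -0.0148 and 0.680 with a sample left out, Chrm2 for CA3 and DG at -0.0883 and Hrh1 at 0.0376 with the fixed replicate block, and, without DG F7 to F9, Chrm2 at -0.124 and Adcy9 in DG at -0.126, or -0.0604 without PC F2, PC M3 and GP M3 as well.

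Leaving out each sample in turn gave 148 to 197 for the F-test, 13 to 31 for BLA, 1 to 12 for CA3, 32 to 42 for CPU, 43 to 132 for DG, 52 to 127 for FC_WT, 77 to 92 for GCL, 0 to 1 for GP, 31 to 46 for HYP, 62 to 199 for PC, 36 to 74 for SN, 13 to 32 for TH, 0 to 57 for CA3 and DG, 0 to 75 for PC and GCL, 17 to 29 for CPU and GP, 1 to 6 for 3TG and 15 to 17 for the code letters. A lone FC_WT sample is assumed to vary like the other groups. PC and GCL gave 49 without PC F1 and 75 without PC F4. Same-region nearest neighbours numbered 18 to 38 over the settings and 32 to 36 with a sample left out, and the within minus between difference lay between 0.0104 and 0.0543.

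Of the values of single named CpGs, 1734 kept their direction and side of the threshold under the alternatives, 74 lost and 27 gained a call, and with a sample left out 6389 kept both, 101 lost and 30 gained a call. The number of arrays limits the precision, and signal over background was not used here.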

Other observations

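The tests of frontal cortex and the splits were set before their values were computed; Chrm2 was singled out after its values were seen.

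The single CA1 sample from 3TG mice entered no comparison. Spnb4 was at 0.365 in it, near the 0.306 to 0.346 of 3TG frontal cortex and below the 0.508 to 0.591 of wild-type frontal cortex. F2r was at 0.254, F2rl2 at 0.788 and Tbxa2r at 0.291. The mean of its X-linked CpGs was 0.457.

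Chrm2 was between 0.539 and 0.591 in DG F7, F8 and F9, at 0.519 and 0.541 in FC_WT, between 0.568 and 0.620 in FC_3TG and at 0.565 in the CA1 sample, against 0.791 and 0.777 in the other DG samples and 0.710 to 0.805 in the other 9 regions. Adcy9 was at 0.748, 0.333 and 0.619 in DG F7, F8 and F9 and at 0.144 and 0.191 in FC_WT.

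FC_WT was lower than the other regions at 105 of its calls and higher at 16, but higher at 73 and lower at 71 with quantile normalization and at 82 and 43 with centring; its titles share a form with those of DG F7, F8 and F9. Across autosomal CpGs the difference of those 3 samples from the other DG samples correlated with that of FC_WT from the other regions at r = 0.341 (rank correlation 0.580), just over the 0.3 set beforehand, where simulated samples without effects gave 0.00548. A batch that goes with this form of title may thus account for part of the frontal cortex and DG calls. Frontal cortex itself cannot be told apart from such a batch. FC_3TG deviated from the other regions as FC_WT did (r = 0.832, simulated 0.0455). The difference of the CA1 sample from CA3 correlated with that of FC_WT as well (r = 0.678). CA3 enters both of these differences, and no simulated value was made for this r. No frontal cortex sample shares its replicate code with another region. A difference of animals stays open and untested.

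Splits of the 53 samples into groups of the real sizes were refitted, 100 per result with the real one included. Chance can be excluded for the F-test (170 CpGs in the real split, at most 9 in the others). Only the real split reached the count of CA3 (8 against at most 2), DG (92 against 68), GCL (85 against 38), HYP (38 against 23), PC (178 against 11), SN (57 against 4) and TH (27 against 6). For BLA and CPU 2 splits gave as many. The highest others there, 34 and 76, exceeded the real 26 and 38, which points to a structure of the samples. These splits mix all 11 regions at once, so real differences of the other regions widen the spread in them. They therefore cannot exclude chance for a single region. Within pairs of regions chance is excluded for CPU and GP (1; 23 against 11) and not for CA3 and DG (10; 25 against 77), and the count of 77 points to a structure of the samples too. For GP and for PC and GCL, with 0 calls, each of the 100 splits gives as many by construction, so the splits decide nothing; the highest others gave 38 and 128. Splits were run only for groups of at least 3 samples, so not for FC_WT or the 3TG comparison.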
